A study of Mus musculus with 12 samples.

How the data were processed

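Expression was measured on 12 Affymetrix-type oligonucleotide arrays from embryonic day 8.0 mouse embryos, 4 groups of 3 arrays. The groups cross the ER71 genotype (wild-type or mutant) with an EYFP sort (positive or negative). Per the labels, cells were released with trypsin and separated on a cell sorter. Total RNA was extracted with Trizol and labelled with biotin using the MessageAmpII-Biotin Enhanced Kit, with RNA amplification, per the labels. The deposited values were used as given: log2 expression values made by the authors with RMA, per the submitters' processing notes. The RMA version and its background and normalization settings are not given in the sources used here, and scanner files were not used here. Array medians lay between 6.98 and 7.06. The number of arrays, 3 per group, limits the precision of every value.

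Of 45101 probe sets, 64 were array controls. The platform table named 34945 probe sets with 1 gene symbol and 932 with several, and it did not list the other 9160. The RefSeq gene table of the assembly GRCm38.p6, used for names only, held the genes of 34741 named probe sets and changed 0 symbols. Each gene was represented by the probe set with the highest mean over the 12 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. No genome positions are given because no probe coordinates were available. No filter on dim probe sets was applied.

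Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) in 1 model of the 4 groups, which leaves 8 residual degrees of freedom and lets all groups share an estimate of the spread. The 5 contrasts were wild-type positive against wild-type negative, mutant positive against wild-type positive, mutant positive against mutant negative, mutant negative against wild-type negative, and the interaction, which is the positive-negative difference in mutants minus that in wild types. P-values were adjusted by the Benjamini-Hochberg method over genes within a contrast, and an adjusted p under 0.05 counted as past the threshold, with no minimum fold. Errors of log2 differences are limma's moderated standard errors (SE), and errors of group means are standard deviations (SD). All of limma's tests were two-sided.

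Gene lists were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over 21 lists and 5 contrasts together, 105 tests. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it. On all arrays, list calls printed without an estimated-correlation value also passed with it, at camera adjusted p from 0.000554 to 0.0445. With the preset correlation the values were far smaller, down to 1.38e-62, and rest on list genes varying almost independently. The lists were endothelial genes, haematopoietic regulators and early surface markers, primitive erythroid genes, cardiac regulators, cardiac sarcomere and muscle products, primitive streak and nascent mesoderm, paraxial mesoderm and somite, lateral plate with extraembryonic mesoderm and allantois, definitive endoderm and epithelium, visceral and yolk sac endoderm, neural ectoderm, neural crest, trophoblast, Notch, BMP with TGF-beta and Wnt pathway genes, cell cycle, p53 targets and apoptosis, hypoxia and glycolysis, dissociation stress and immediate early genes, and ribosomal proteins. Some genes sit in more than 1 list. The mean, the median and the test direction differed in sign in 11 of the 105 tests, 0 of which passed the threshold.

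The contrasts, the tests, the gene lists, the first group of alternative settings and the rule for named genes were set before the data were examined. The rule takes a fixed set of key genes in every contrast and the 8 largest rises and 8 largest falls per contrast among genes past the threshold whose arrays do not overlap between groups (for the interaction, past the threshold). It also takes up to 4 members per list with the smallest unadjusted p, and leaves out clone-type names. Genes named outside the rule are identified as such.

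The replicate numbers were checked for pairing by correlating the deviations from group means of same-numbered positive and negative arrays across genes, which are not independent replicates. These correlations were 0.190, 0.102 and 0.202 in wild types and 0.554, 0.403 and 0.413 in mutants. Their mean of 0.311 was higher than under any of the other assignments of positive to negative arrays within a genotype (highest 0.246; exact permutation p = 0.0278, one-sided, 36 assignments). Across genotypes, same-numbered arrays gave -0.244 to 0.0487. The numbers were therefore read as pairing the positive and negative arrays of a genotype, from the data and not from the labels. A block for these pairs was added as an alternative after the data were seen.

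The first group of alternative settings comprised the mean of all probe sets of a gene, no collapse to genes, leaving out probe sets shared between transcripts, a filter on dim probe sets, median centring, quantile normalization again, array weights, trend and robust moderation, only the groups of a contrast in the model, the replicate number as a block, a minimum of 2-fold, an adjusted p under 0.01, the other list tests, and leaving out each array in turn. After the data were seen, blocks for the pairs within a genotype, the actin 3′ to 5′ difference as a covariate, and the omission of arrays in doubt were added. Overlaps and correlations between contrasts sharing a group were set beside 20 simulations without effects.

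The procedure was tested on simulated data for all 18193 genes. With 67 genes changed 2-fold, it recovered 83.6% for wild-type positive against wild-type negative, 85.1% for mutant positive against wild-type positive, 85.1% for mutant positive against mutant negative, 79.1% for mutant negative against wild-type negative, and 58.2% for the interaction. At 1.5-fold the corresponding shares were 34.3%, 37.3%, 46.3%, 37.3% and 5.97%, and at 4-fold, with 66 genes changed, 100%, 100%, 98.5%, 98.5% and 92.4%. Between 1 and 11 unchanged genes were called per contrast. In each contrast, 3 of 3 lists shifted by 0.5 log2 were recovered and 0 of 18 others were called. The simulated genes varied independently of each other, so this does not measure false list calls where the genes of a list vary together.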

Results

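Expression was compared between 4 groups of 3 arrays from embryonic day 8.0 mouse embryos of a mixed line. The embryos were wild-type or mutant for ER71, now named Etv2, which encodes an ETS-family transcription factor required for blood and endothelial development. Cells were sorted by EYFP, a yellow fluorescent protein, into positive and negative fractions, called positive and negative cells here. The labels do not say which sequences drive EYFP. They also do not say whether the 3 samples of a group came from separate animals or pools. The p-values thus measure the spread between these samples, which may be technical in part or, in mutants, as a whole. Arrays of the same group correlated at r = 0.981 to 0.991 and arrays of different groups at r = 0.958 to 0.991 across genes, which are not independent replicates. Signal over background was not given. Differences from values below the 25th percentiles of the arrays (5.62 to 5.69 log2), such as Cdh5 in wild-type negative cells (mean 4.79), therefore have an uncertain size.

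Etv2, the targeted gene, had log2 RMA values of 10.72, 10.70 and 11.36 in wild-type positive cells and 7.58, 7.50 and 7.85 in wild-type negative cells. In mutants the values were 7.40, 7.26 and 7.28 in positive cells and 7.49, 7.43 and 7.24 in negative cells. The 3 wild-type positive arrays thus stood above the other 9. All 6 mutant arrays lay below the wild-type negative arrays, the closest at 7.49 against 7.50, though mutant and wild-type negative cells did not differ past the threshold. The labels do not give the deleted part of the gene, so the probe set may lie outside it and may check nothing about the deletion itself. Etv2 was 9.74-fold higher in wild-type positive than in wild-type negative cells (3.28 ± 0.17 log2, SE, n = 3 per group; limma, adjusted p = 3.33e-07). Between mutant positive and mutant negative cells it differed by -0.07 log2 (adjusted p = 0.918).

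Some arrays stood apart from their group. Both wild-type arrays numbered 1 had high Eif2s3y, a Y-linked gene (11.2 in negative and 10.8 in positive cells, against 4.11 to 4.53 on the other 10 arrays), together with low Xist (8.19 and 10.3, against 13.4 to 14.0). Uty, also Y-linked, was highest there (6.34 and 6.82), while Kdm5d did not separate them. These values point to male cells, so the wild-type samples were not all technical repeats. No mutant array had high Eif2s3y, so this sign of sex is partly confounded with genotype. Mutant positive array 1 had Afp, a yolk sac endoderm gene, at 11.98, against 5.02 and 4.04 on the other mutant positive arrays. Mutant negative array 2 had the embryonic globin Hbb-y at 11.55, against 5.01 and 4.71, while wild-type negative arrays had 10.80, 5.59 and 11.94. The actin 3′ minus 5′ signal, a sign of RNA integrity, was 1.53 ± 0.11 log2 (SD, n = 3) in mutant positive cells, 2.40 ± 0.78 in wild-type positive, 2.26 ± 0.43 in mutant negative and 2.21 ± 0.82 in wild-type negative cells. The difference of mutant positive cells from wild-type positive cells was -0.87 (exact permutation p = 0.3) and from mutant negative cells -0.73 (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow; both two-sided).

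In wild-type embryos, the comparison of positive with negative cells shows which genes accompany the reporter when Etv2 is present. Endothelial and blood genes were among those higher in positive cells. Cdh5, the endothelial junction protein VE-cadherin, rose by 5.44 ± 0.11 log2 (limma, adjusted p = 2.25e-10), and Tal1, a transcription factor of early blood formation, rose by 5.15 ± 0.18 log2, or 35.6-fold (adjusted p = 9.19e-09). Fli1, an ETS factor of endothelium and blood, rose by 4.44 ± 0.23 log2, the angiopoietin receptor Tek by 4.46 ± 0.28, the VEGF receptor Kdr by 3.17 ± 0.16 and Lmo2, a partner of Tal1, by 2.88 ± 0.25 (adjusted p from 3.33e-07 to 2.35e-05). Neural, somite and epithelial genes were lower, the epithelial list with adjusted p = 0.0631 with an estimated correlation. Cdh1, the epithelial cadherin, fell by 4.53 ± 0.48 log2 (adjusted p = 0.000105), and Pax6, a neural transcription factor, fell by 2.65 ± 0.23 (adjusted p = 2e-05).

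Of 34 endothelial genes, 33 rose in wild-type positive cells and 33 rose when adjusted over the list alone (list mean 2.91 log2, camera adjusted p = 1.38e-62). Further members were the junction protein Cldn5 (5.25 ± 0.13 log2), the matrix protein Mmrn2 (5.26 ± 0.16) and Flt4, the VEGF-C receptor (3.79 ± 0.11). Among 22 haematopoietic regulators 11 rose and 11 did not pass, against 12 that rose and 1 that fell when adjusted over the list alone (mean 1.22, adjusted p = 3.35e-11), with Hhex at 3.83 ± 0.18 and Lyl1 at 3.38 ± 0.20. Gata1, the erythroid transcription factor, rose by 1.60 ± 0.21, Gata2 by 0.95 ± 0.17 and the junction protein Pecam1 by 0.74 ± 0.15. Runx1, a regulator of definitive blood, did not pass at its brightest probe set (0.25 log2, adjusted p = 0.29), whereas another probe set for it gave 2.23 ± 0.16 (adjusted p = 8.68e-06). Primitive erythroid genes rose in 11 of 17 cases, 15 when adjusted over the list alone (mean 2.47, adjusted p = 2.73e-18), including the anion exchanger Slc4a1 (4.80 ± 0.28), the erythroid factor Klf1 (3.33 ± 0.14) and the embryonic globin Hba-x (5.09 ± 0.55). The embryonic globin Hbb-bh1 was higher by 5.17 ± 1.24 (adjusted p = 0.0249), but it did not pass without negative array 1 or 2 or without positive array 1, 2 or 3 (adjusted p 0.0582 to 0.0822), nor under 6 of 27 alternatives in all (up to 0.132). The 8 largest rises also held Ctla2b (6.59 ± 0.14), Klhl4, Ctla2a, Tmem204 and the blood-cell nuclear protein Hemgn (5.53 ± 0.28).

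Dissociation stress genes rose in 7 of 17 cases, 10 when adjusted over the list alone (mean 0.74, adjusted p = 5.46e-07), including the immediate early genes Atf3 (2.19 ± 0.24) and Junb (1.17 ± 0.20). Of 19 BMP and TGF-beta genes 5 rose, 2 fell and 12 did not pass, and the list did not pass with camera (mean 0.26, adjusted p = 0.13), but passed with fry (adjusted p = 0.00511) and, with camera, without negative array 2 (0.0498). Those that rose included Tgfbr2 (2.77 ± 0.19), Acvrl1 and Eng, which encode receptors also used by endothelial cells. Of 16 Notch genes 3 rose and 3 fell (mean -0.06, adjusted p = 0.848), with the target gene Hey1 at 1.19 ± 0.13.

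Several lists were lower in wild-type positive cells. Neural ectoderm genes fell in 13 of 21 cases, 16 with 1 rise when adjusted over the list alone (mean -1.43, camera adjusted p = 1.23e-13), and besides Pax6 the retinoic acid binding protein Crabp2 fell by 2.70 ± 0.24. Paraxial mesoderm and somite genes fell in 10 of 17 cases, 15 when adjusted over the list alone (mean -1.28, adjusted p = 5.28e-13), including the dermomyotome factor Pax3 (-2.03 ± 0.20) and the Notch ligand Dll1 (-1.37 ± 0.16). Of 8 neural crest genes 4 fell and 1, the endothelin receptor Ednrb, rose, and 6 fell with 1 rise when adjusted over the list alone (mean -0.89, adjusted p = 0.000393). Wnt pathway genes fell in 9 of 19 cases, 12 when adjusted over the list alone (mean -0.72, adjusted p = 6.08e-09), among them the target Axin2 (-1.28 ± 0.14) and the secreted antagonists Sfrp1 and Sfrp2. Definitive endoderm and epithelial genes fell in 9 of 15 cases, 12 when adjusted over the list alone (mean -1.86, adjusted p = 5.09e-13, and adjusted p = 0.0631 with an estimated correlation), including the forkhead factor Foxa1 (-2.64 ± 0.23) and the surface protein Epcam (-4.23 ± 0.42). Primitive streak genes fell in 8 of 18 cases, 10 when adjusted over the list alone (mean -0.70, adjusted p = 1.5e-07, and adjusted p = 0.0617 with an estimated correlation), with Pdgfra, a mesodermal growth factor receptor, at -1.18 ± 0.18. Of 14 p53 and apoptosis genes 3 fell, and 3 when adjusted over the list alone (mean -0.35, adjusted p = 0.0289, and adjusted p = 0.221 with an estimated correlation). That call was also lost without negative array 3 (adjusted p = 0.0769) or positive array 2 (0.0522) or 3 (0.0787).

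The remaining lists did not pass in wild types. Cardiac regulators had a mean of -0.06 log2 (2 of 21 higher, 0 lower, adjusted p = 0.744), with Mef2c at 1.04 ± 0.18 and Hopx at 1.15 ± 0.22, while Gata4, Nkx2-5, Tbx5 and Isl1 did not pass (-0.18, -0.39, -0.53 and -0.09). Cardiac sarcomere genes had a mean of -0.09 (0 of 26 past the threshold, adjusted p = 0.657), lateral plate genes 0.23 (2 higher, 3 lower of 19, adjusted p = 0.31), trophoblast genes -0.15 (2 of 11 lower, adjusted p = 0.474), hypoxia and glycolysis genes 0.18 (2 of 18 higher, adjusted p = 0.098, and 0.0498 without negative array 2), cell cycle genes -0.02 (1 of 19 lower, adjusted p = 0.72) and ribosomal protein genes -0.06 (0 of 11, adjusted p = 0.523). Of 17 visceral endoderm genes 3 were higher and 4 lower (mean -0.70, adjusted p = 0.446). This list passed without mutant positive array 1 (adjusted p = 0.0222), which lies outside this comparison but enters the shared estimate of the spread.

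Counted over all genes, 1499 of 18193 passed in wild types, 843 higher and 656 lower, and 474 and 275 of them changed at least 2-fold. The 3 arrays of each group did not overlap for 4589 genes, 25.2% against 10% by chance. With the positive-negative pairs as a block, 2160 genes passed, 1119 higher and 1041 lower. Of the 21 lists, 11 passed, and 8 passed with an estimated correlation. Without both wild-type arrays numbered 1, which differ in Xist and Eif2s3y, 760 genes passed, and without wild-type negative array 1, 2 or 3 the lower genes numbered 424, 410 and 405.

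**Figure D1:**
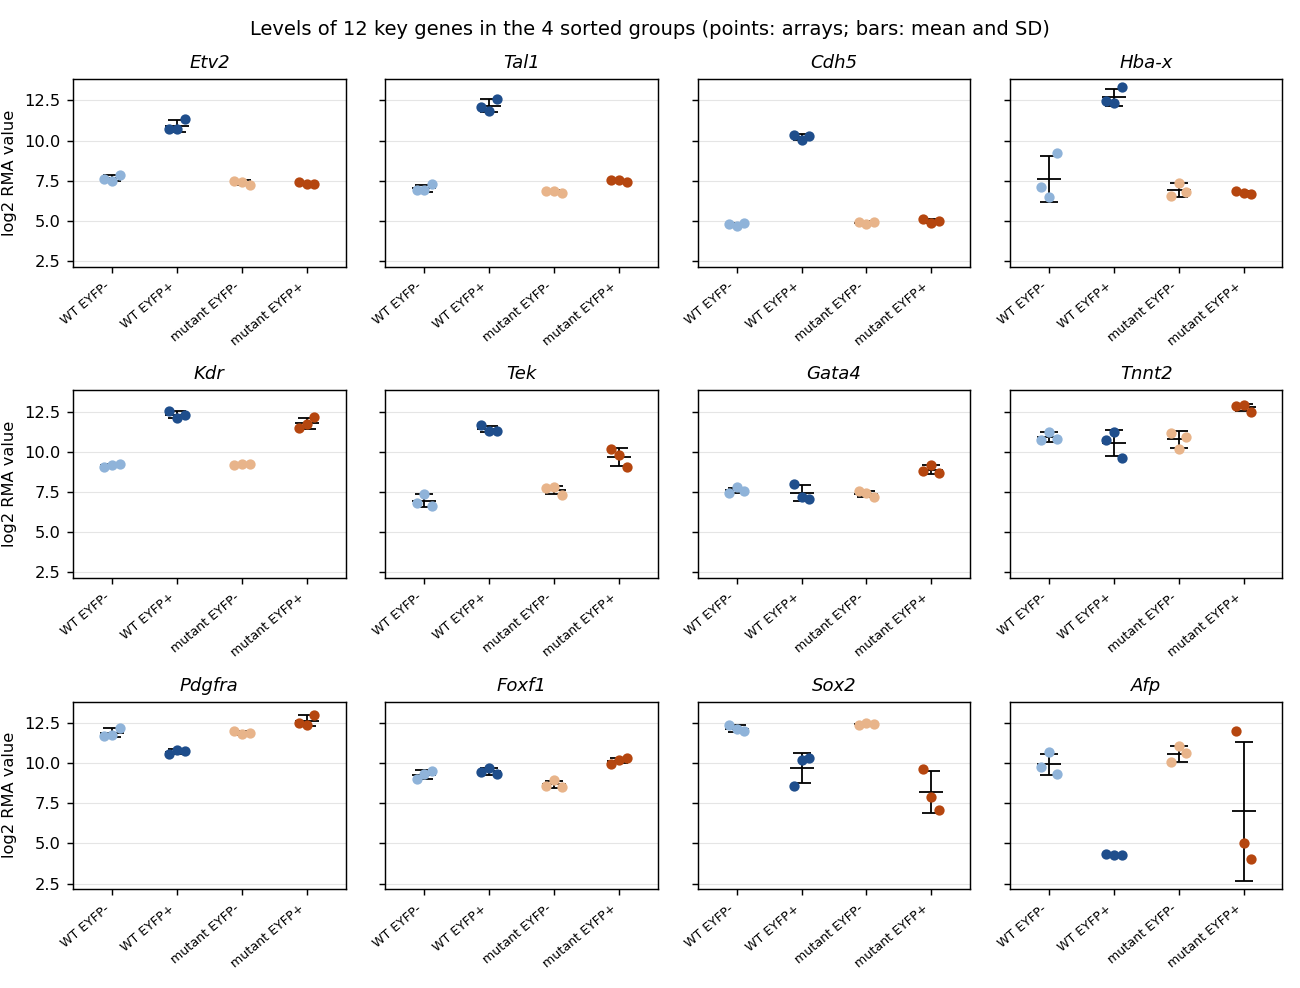
Log2 RMA values of 12 genes in the 4 groups; each point is 1 array, and bars give the mean and SD of 3 arrays. Cdh5 and Tal1 were high in wild-type positive cells alone among the 4 groups, whereas Kdr was also high in mutant positive cells and Gata4 and Tnnt2 were highest there.

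The comparison of mutant with wild-type positive cells addresses what changes in the sorted fraction when Etv2 is mutated. Blood and endothelial genes were lower in the mutant and lateral plate and heart genes higher, with the heart muscle list at adjusted p = 0.0736 with an estimated correlation. Cdh5 fell by 5.24 ± 0.11 log2 (limma, adjusted p = 3.4e-10), Tal1 by 4.69 ± 0.18 (adjusted p = 2.62e-08) and Hba-x by 5.94 ± 0.55 (adjusted p = 4.87e-05). Tbx5, a transcription factor of the heart fields, rose by 1.35 ± 0.16 (adjusted p = 0.00028), Gata4, a heart and endoderm factor, by 1.48 ± 0.23 (adjusted p = 0.00191), and Myl7, the atrial myosin light chain, by 2.52 ± 0.35 (adjusted p = 0.00114). Etv2 itself fell by 3.62 ± 0.17 (adjusted p = 1.65e-07).

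Of 34 endothelial genes, 31 fell and 3 did not pass, and 34 fell when adjusted over the list alone (mean -2.50 log2, camera adjusted p = 5.56e-52). Fli1 fell by 4.34 ± 0.23, Cldn5 by 4.86 ± 0.13 and Tek by 1.76 ± 0.28, whereas Kdr did not pass (-0.54 ± 0.16, adjusted p = 0.0715). Haematopoietic regulators fell in 12 of 22 cases, and 12 when adjusted over the list alone (mean -1.20, adjusted p = 3.99e-12), including Lmo2 (-2.30 ± 0.25), Hhex (-4.17 ± 0.18) and Gata1 (-1.60 ± 0.21). Runx1 again differed between probe sets, with -0.29 at the brightest (adjusted p = 0.183) and -2.21 ± 0.16 at another (adjusted p = 1.06e-05). Of 17 primitive erythroid genes 14 fell, and 15 when adjusted over the list alone (mean -3.12, adjusted p = 2.68e-20). The embryonic globins Hbb-y and Hbb-bh1 fell by 9.63 ± 1.77 and 8.45 ± 1.24 (adjusted p = 0.0063 and 0.00155). Hbb-y had a mean of 14.65 ± 0.19 (SD, n = 3) in wild-type positive cells, near the array maxima of 14.97 to 15.17, and 5.02 ± 0.34 in mutant positive cells, below the 25th percentiles of the arrays, so the size of its difference is uncertain. The same holds for Hbb-bh1, here and in the other comparisons, with 14.56 to 14.82 on the wild-type positive arrays.

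Cardiac regulators rose in 15 of 21 cases, 17 when adjusted over the list alone (mean 1.15 log2, camera adjusted p = 5.84e-15). Besides Gata4 and Tbx5, Gata6 rose by 1.19 ± 0.11, Hand2, a heart and limb factor, by 1.57 ± 0.16 and Tbx2, a factor of the non-chamber heart, by 2.70 ± 0.24. Nkx2-5, an early heart factor, rose by 1.27 ± 0.24 (adjusted p = 0.00748), a call lost under 1 of 26 alternatives (0.0504). Isl1, a factor of heart progenitors, rose by 0.78 ± 0.18 (adjusted p = 0.0232), a call lost without wild-type positive array 1 or mutant positive array 1 or 3 (0.0713 to 0.0805) and under 7 of 26 alternatives in all (up to 0.128). Cardiac sarcomere genes rose in 18 of 26 cases, 22 with 1 fall when adjusted over the list alone (mean 1.44, adjusted p = 2.33e-16, and adjusted p = 0.0736 with an estimated correlation), including the troponins Tnnt2 (2.23 ± 0.36) and Tnni1 (2.26 ± 0.28). Lateral plate and allantois genes rose in 11 of 19 cases, 17 when adjusted over the list alone (mean 1.05, adjusted p = 3.37e-13), including Prrx1, a mesenchymal factor (1.47 ± 0.19), Bmp4 (1.20 ± 0.20) and Vcam1, an adhesion molecule (1.61 ± 0.23). Pdgfra rose by 1.93 ± 0.18 (adjusted p = 4.35e-05). Dimmer probe sets of Gata4, Tbx5, Gata6 and Vcam1 did not pass (0.10, 0.05, 0.38 and 0.07 log2 at 1 such probe set of each).

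Wnt pathway genes rose in 6 of 19 cases, 7 when adjusted over the list alone (mean 0.57, camera adjusted p = 0.000329, and adjusted p = 0.0715 with an estimated correlation). They included Wnt2 (2.05 ± 0.27), a ligand made by heart and allantois progenitors, the target Axin2 (1.01 ± 0.14), and the antagonists Sfrp1 (2.08 ± 0.26) and Dkk1 (1.65 ± 0.24). Of 16 Notch genes 5 fell and 1 rose, with the same counts when adjusted over the list alone (mean -0.24, adjusted p = 0.0472, and adjusted p = 0.112 with an estimated correlation), including the receptor Notch1 (-1.74 ± 0.22), the feedback gene Nrarp (-1.21 ± 0.18) and Hey1 (-0.85 ± 0.13). The Notch list did not pass without wild-type positive array 1 or 2, mutant positive array 1 or mutant negative array 1 or 2 (adjusted p 0.05 to 0.0999). Of 18 streak genes 1, Pdgfra, rose and 17 did not pass (4 rose when adjusted over the list alone, mean 0.34, adjusted p = 0.0283, and adjusted p = 0.4 with an estimated correlation). The streak call was lost without wild-type positive array 1 (0.0639) or 3 (0.0885) or mutant positive array 2 (0.0745). Stress genes fell in 2 of 17 cases, Atf3 (-1.88 ± 0.24) and Dusp1 (-0.89 ± 0.12), and 2 when adjusted over the list alone (mean -0.34, adjusted p = 0.0405, and adjusted p = 0.243 with an estimated correlation). The stress call was lost without wild-type positive array 1 or 3 or mutant positive array 1 or 2 (0.07 to 0.121). Neural genes had a mean of 0.04 (3 of 21 higher, 0 lower, camera adjusted p = 0.736). Somite genes had 0.34 (3 higher, 1 lower of 17, adjusted p = 0.221) and epithelial genes 0.18 (2 of 15 higher, 0 lower, adjusted p = 0.454). None of these lists passed, though single members did. 4 more lists did not pass but did without 1 array. Visceral endoderm genes had a mean of 0.50 (adjusted p = 0.173), with 0.78 without mutant positive array 2 (adjusted p = 0.0332) and 0.85 without mutant positive array 3 (adjusted p = 0.019). Both omissions keep mutant positive array 1, the array with high Afp, which raises this mean. Hypoxia genes had 0.27 (adjusted p = 0.0853), with 0.39 without mutant positive array 3 (adjusted p = 0.0104). Ribosomal protein genes had 0.18 (adjusted p = 0.098), with 0.26 without mutant positive array 3 (adjusted p = 0.0257) and 0.24 without wild-type positive array 3 (adjusted p = 0.0333). Trophoblast genes had 0.42 (adjusted p = 0.0811), with 0.54 without mutant positive array 2 (adjusted p = 0.0442).

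Between mutant and wild-type positive cells, 1450 genes passed, 769 higher and 681 lower, and 274 and 373 of them differed at least 2-fold. The arrays did not overlap for 4672 genes, 25.7% against 10% by chance. Of the lists, 10 passed, and 5 passed with an estimated correlation. With only the 6 arrays compared in the model 844 genes passed (385 higher, 459 lower), and 908 passed (419 and 489) with the actin 3′ minus 5′ signal, lower in mutant positive cells, as a covariate. Without mutant positive array 1 the counts were 446 higher and 586 lower, without wild-type positive array 2 612 and 653, and without wild-type positive array 3 544 and 566, so which direction held more genes depended on the arrays and settings.

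In mutants, the comparison of positive with negative cells shows what still accompanies the reporter without intact Etv2. Kdr rose by 2.57 ± 0.16 log2 (limma, adjusted p = 4.62e-05) and Tek by 2.04 ± 0.28 (adjusted p = 0.00136), while Cdh5, Fli1 and Hba-x did not pass (0.10, 0.34 and -0.16 log2). Heart and lateral plate genes were higher in positive cells: Gata4 rose by 1.52 ± 0.23 (adjusted p = 0.00229), Tbx20, a heart factor, by 2.62 ± 0.27 (adjusted p = 0.000304), and Foxf1, a factor of splanchnic and extraembryonic mesoderm, by 1.48 ± 0.17 (adjusted p = 0.000612). Neural genes were lower, with Sox2, a neural and pluripotency factor, falling by 4.22 ± 0.57 (adjusted p = 0.00135).

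Cardiac regulators rose in 15 of 21 cases in mutant positive cells, 19 when adjusted over the list alone (mean 1.31 log2, camera adjusted p = 3.26e-26), including Gata6 (1.88 ± 0.11), Tbx5 (0.99 ± 0.16) and Isl1 (1.07 ± 0.18). Cardiac sarcomere genes rose in 20 of 26 cases, 22 when adjusted over the list alone (mean 1.43, adjusted p = 8.53e-24), with Myl7 at 2.40 ± 0.35 and Tnni1 at 2.21 ± 0.28. Of 19 lateral plate genes 14 rose, and 17 when adjusted over the list alone (mean 1.55, adjusted p = 2.75e-26), including Vcam1 (2.72 ± 0.23), the collagen Col3a1 (3.09 ± 0.38) and Pitx1, a hindlimb and mesoderm factor (2.56 ± 0.21). BMP pathway genes rose in 6 of 19 cases, and 6 when adjusted over the list alone (mean 0.53, adjusted p = 4.49e-06), among them Bmp4 (1.73 ± 0.20) and the antagonists Bambi (1.43 ± 0.16) and Smad6 (1.75 ± 0.21). The largest rises also held the collectins Colec11 (3.98 ± 0.55) and Colec10 and the mesothelial and heart-progenitor factor Tcf21 (2.81 ± 0.33). The actin 3′ minus 5′ signal moved with these lists, at -0.73 in mutant positive relative to mutant negative cells. With this signal as a covariate, 693 genes passed within mutants (404 higher, 289 lower), against 975 without it.

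Endothelial genes rose in 5 of 34 cases in mutants, 8 when adjusted over the list alone (mean 0.37, camera adjusted p = 1.83e-05, and adjusted p = 0.0823 with an estimated correlation). Besides Kdr and Tek these included the apelin receptor Aplnr (1.18 ± 0.18) and Plvap, a protein of endothelial diaphragms (1.54 ± 0.25). Of 22 haematopoietic regulators 1, Cbfa2t3, was higher and 1, the progenitor factor Myb, lower (mean 0.02, adjusted p = 0.86). The Cbfa2t3 call was lost under 16 of 27 alternatives, among them the positive-negative pairs as a block (limma adjusted p = 0.0638). No erythroid gene passed (mean -0.35, adjusted p = 0.215), and the embryonic globins on mutant negative array 2 lower this mean. Tal1 and Lmo2 did not pass (0.66 ± 0.18 and 0.77 ± 0.25, adjusted p = 0.0559 and 0.124), but both passed with the positive-negative pairs as a block (0.00838 and 0.0296). Stress genes rose in 3 of 17 cases, 8 when adjusted over the list alone (mean 0.60, adjusted p = 1.91e-07). Hypoxia and glycolysis genes rose in 2 of 18 cases, among them the growth factor Vegfa (0.70 ± 0.09), and in 4 when adjusted over the list alone (mean 0.26, adjusted p = 0.014, and adjusted p = 0.396 with an estimated correlation). That call was lost without mutant negative array 3 (0.0554) or mutant positive array 1 (0.089) or 2 (0.0501).

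Neural ectoderm genes fell in 14 of 21 cases in mutant positive cells, 17 when adjusted over the list alone (mean -1.66 log2, camera adjusted p = 2.73e-18), including Sox1 (-4.41 ± 0.60), Pax6 (-2.55 ± 0.23) and the proneural factor Neurog2 (-2.89 ± 0.36). Neural crest genes fell in 4 of 8 cases with 1 rise, Ednrb (5 falls when adjusted over the list alone, mean -0.83, adjusted p = 0.00246). Epithelial genes fell in 10 of 15 cases with 1 rise, 11 and 2 when adjusted over the list alone (mean -1.42, adjusted p = 1.29e-08, and adjusted p = 0.124 with an estimated correlation), including Cdh1 (-3.88 ± 0.48) and Epcam (-3.21 ± 0.42). Somite genes fell in 6 of 17 cases, 9 when adjusted over the list alone (mean -0.94, adjusted p = 2.11e-08, and adjusted p = 0.0631 with an estimated correlation), including Dll1 (-2.22 ± 0.16) and Pax3 (-2.25 ± 0.20). Streak genes fell in 5 of 18 cases with 1 rise, 9 and 1 when adjusted over the list alone (mean -0.47, adjusted p = 4.35e-05, and adjusted p = 0.116 with an estimated correlation). Notch genes fell in 4 of 16 cases with 1 rise, 6 and 1 when adjusted over the list alone (mean -0.34, adjusted p = 0.0157, and adjusted p = 0.0631 with an estimated correlation). Wnt genes fell in 4 of 19 cases with 1 rise, 7 and 1 when adjusted over the list alone (mean -0.20, adjusted p = 0.0351, and adjusted p = 0.27 with an estimated correlation). The Wnt call was lost without mutant negative array 2 (0.0626) or mutant positive array 3 (0.129). Visceral endoderm genes did not pass (mean -0.43, adjusted p = 0.8), but fell by 1.06 log2 on average without mutant positive array 1, the array with high Afp (adjusted p = 8.16e-06).

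Within mutants, 975 genes passed, 558 higher and 417 lower, and 329 and 214 of them differed at least 2-fold. Arrays did not overlap for 3545 genes, 19.5% against 10% by chance. With the positive-negative pairs as a block, 1486 genes passed, 872 higher and 614 lower. The split was 368 higher and 314 lower without mutant negative array 3, 420 and 257 without mutant positive array 2, 480 and 275 without mutant positive array 3, and 344 and 384 without both mutant positive array 1 and mutant negative array 2. Of the lists, 14 passed and 7 passed with an estimated correlation.

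**Figure D2:**
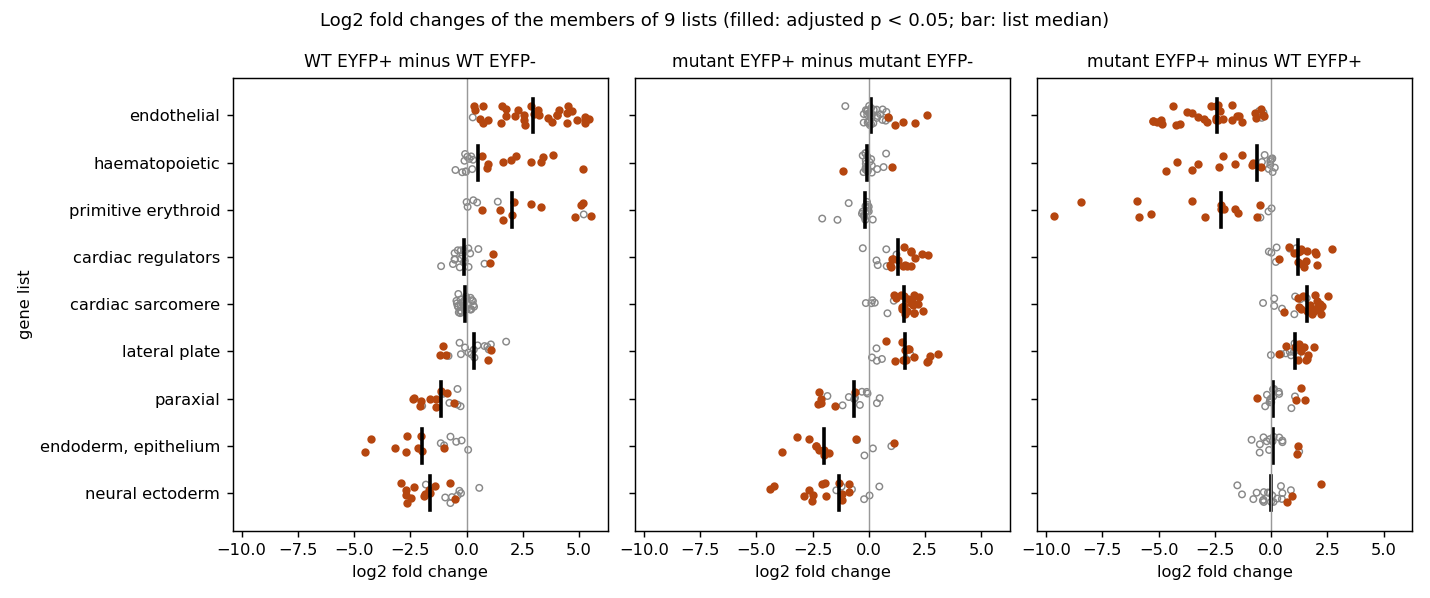
Log2 differences of the members of 9 gene lists in 3 comparisons; each point is 1 gene, filled where its adjusted p is under 0.05, and bars give the list median. Endothelial and erythroid genes lay mostly above 0 in wild-type positive cells and near 0 in mutant positive cells, whereas cardiac and lateral plate genes lay mostly above 0 in mutant positive cells.

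Whether the positive-negative difference itself differed by genotype was tested by the interaction. It was smaller in mutants for blood and endothelial genes and larger for heart regulators and lateral plate genes. Cdh5 fell by 5.34 ± 0.15 log2 in the interaction (limma, adjusted p = 1.34e-08), while Gata6 rose by 1.72 ± 0.16 (adjusted p = 1e-04) and Vcam1 by 2.79 ± 0.32 (adjusted p = 0.000627). Of 34 endothelial genes 25 were lower in the interaction, 32 when adjusted over the list alone (mean -2.54, camera adjusted p = 2.15e-58). Of the 33 that rose in wild-type positive cells, 5 also rose in mutant positive cells, and 3 of these 5 were lower in the interaction. Kdr retained 81.3% of its wild-type log2 difference and Aplnr 76.3%, and neither passed in the interaction (adjusted p = 0.294 and 0.651). Tek retained 45.8% and Plvap 32.8%, both lower in the interaction (adjusted p = 0.00589 and 0.000496).

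Haematopoietic regulators were lower in the interaction in 6 of 22 cases, 11 when adjusted over the list alone (mean -1.20, adjusted p = 6.72e-14), and erythroid genes in 8 of 17, 15 when adjusted over the list alone (mean -2.82, adjusted p = 2.02e-20). Hbb-bh1 did not pass (-6.56 ± 1.76, adjusted p = 0.0892), but passed at another probe set (-7.17 ± 1.04, adjusted p = 0.00418) and with the pairs as a block (0.0431). Cardiac regulators were higher in 12 of 21 cases, 16 when adjusted over the list alone (mean 1.38, adjusted p = 5.04e-21), including Tbx5 (1.52 ± 0.22) and Hand2 (1.85 ± 0.22). Nkx2-5 did not pass (1.35 ± 0.34, adjusted p = 0.0677), but passed with the pairs as a block (0.0247). Lateral plate genes were higher in 10 of 19 cases, 14 when adjusted over the list alone (mean 1.32, adjusted p = 1.07e-18). Sarcomere genes were higher in 9 of 26 cases, 21 when adjusted over the list alone (mean 1.52, adjusted p = 8.64e-19, and adjusted p = 0.0617 with an estimated correlation). Wnt genes were higher in 3 of 19, 6 when adjusted over the list alone (mean 0.52, adjusted p = 0.000781, and adjusted p = 0.0825 with an estimated correlation). Somite genes did not pass (mean 0.33, adjusted p = 0.273). Neural genes did not pass either (mean -0.24, adjusted p = 0.446), but passed without both wild-type arrays numbered 1 (-0.55, adjusted p = 0.0268) and without mutant positive array 1 and mutant negative array 2 (-0.49, adjusted p = 0.0369). Of 2 more lists that did not pass, p53 targets (mean 0.16, adjusted p = 0.168) passed without mutant negative array 2 (0.24, adjusted p = 0.0385) and ribosomal protein genes (0.10, adjusted p = 0.228) without wild-type negative array 1 (0.19, adjusted p = 0.049).

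Across genes, the interaction counted 469 past the threshold, 177 higher and 292 lower, and 139 and 259 of them by at least 2-fold. With the positive-negative pairs as a block, 797 passed, 378 higher and 419 lower, and without wild-type negative array 2, 299 passed, 82 higher and 217 lower. The higher genes numbered 87 to 117 without wild-type negative array 1 or 3, mutant negative array 2 or 3 or mutant positive array 1. Lower genes outnumbered higher ones in each of these settings, and only the size of the excess depended on the arrays and the block. Of the lists, 10 passed and 5 passed with an estimated correlation.

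Genes higher in positive cells of both genotypes numbered 171, against 25.9 for independent lists, and genes lower in both 216, against 15.0. The log2 differences of the 2 comparisons, which share no array, correlated at r = 0.421 (Spearman's rho 0.262) across genes, which are not independent replicates, with a covariance of 0.0858. Simulated without effects, r was 0.00303. Of the genes higher in wild-type positive cells, 480 were lower in mutant positive cells, against 31.6 for independent lists and 0 in simulations without effects. That pair of comparisons shares the wild-type positive arrays, and its r of -0.693 (rho -0.552) stands beside -0.501 in simulations without effects, with a covariance of -0.172 against -0.0172. Part of this excess may come from the shared arrays. The 31.6 ignores those arrays, and data without effects yield few calls by construction. Neither that value nor the 0 therefore shows how large this part is.

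**Figure D3:**
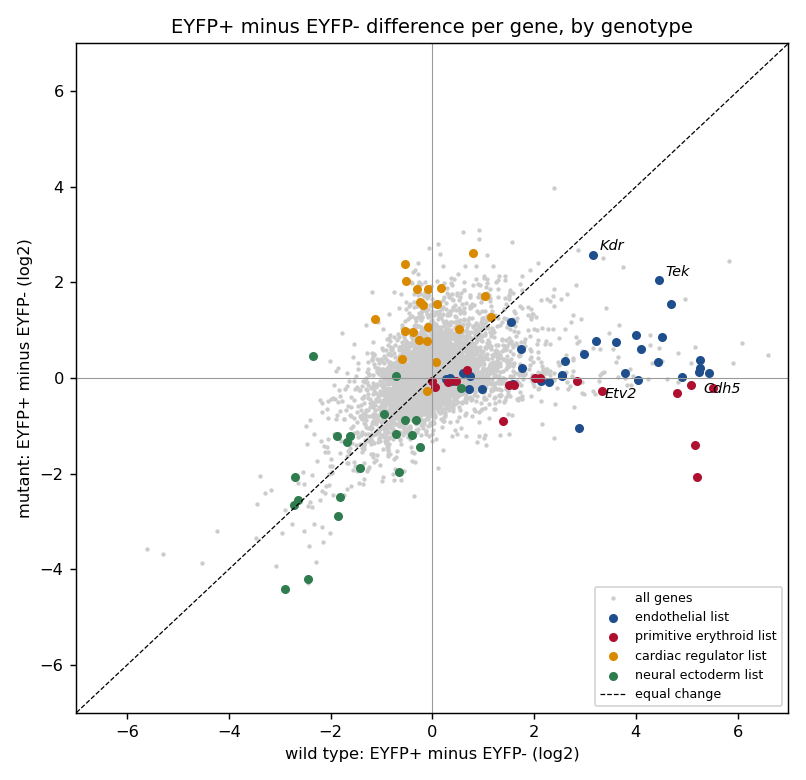
Positive minus negative log2 difference of each gene in wild types (horizontal axis) and in mutants (vertical axis), with endothelial, primitive erythroid, cardiac regulator and neural genes coloured and the dashed line marking equal change. Kdr lay near the line, with 3.17 in wild types and 2.57 in mutants, whereas Cdh5 had 5.44 and 0.10.

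The comparison of mutant with wild-type negative cells asks whether cells outside the reporter fraction changed. By limma, 0 of 18193 genes passed the threshold, 949 had an unadjusted p under 0.05 where 910 would by chance, and the smallest adjusted p was 0.326. Arrays did not overlap for 2039 genes, 11.2% against 10% by chance. Etv2 differed by -0.26 log2 (adjusted p = 0.937), Tal1 by -0.19 (0.942), Kdr by 0.06 (0.984) and Gata4 by -0.22 (0.946).

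At the level of lists, lateral plate genes were lower in mutant negative cells (mean -0.26 log2, camera adjusted p = 4.1e-06), and 5 of 19 members passed when adjusted over the list alone, against 0 over all genes. Vcam1 had -1.18 ± 0.23, Prrx1 -0.76 ± 0.19 and Foxf1 -0.62 ± 0.17. With fry this list did not pass (adjusted p = 0.0587). Cardiac regulators were also lower (mean -0.23, adjusted p = 3.39e-05, and adjusted p = 0.0823 with an estimated correlation), with 3 members adjusted over the list alone. Epithelial genes (mean -0.26, adjusted p = 0.0157), stress genes (-0.19; 0.0197), neural genes (0.27; 0.01) and hypoxia genes (0.20; 0.0414) also passed, with adjusted p = 0.573, 0.174, 0.41 and 0.513 with an estimated correlation, and 2, 1, 0 and 1 members adjusted over the list alone. The epithelial call was lost without wild-type negative array 2 or mutant negative array 2 or 3 (adjusted p 0.149 to 0.154), the neural call without wild-type negative array 3 or mutant negative array 3 (0.0536 and 0.0988), the stress call without wild-type negative array 3 or mutant negative array 1 (0.162 and 0.0522), and the hypoxia call without wild-type negative array 1 or mutant negative array 1 or 2 (0.05 to 0.47). Of the 6 lists past the threshold, 0 passed with fry. Endothelial genes had a mean of 0.04 (adjusted p = 0.848) and haematopoietic regulators 0.00 (adjusted p = 0.991). Primitive erythroid genes had a mean of -0.30 (adjusted p = 0.215) and did not pass, but the mean was -0.55 without mutant negative array 2 (adjusted p = 0.0342) and -0.54 without wild-type negative array 2 (adjusted p = 0.0188), and both passed. Streak genes (mean 0.11, adjusted p = 0.126) passed without wild-type negative array 2 (0.20, adjusted p = 0.00475) or mutant negative array 3 (0.18, adjusted p = 0.01). BMP genes (-0.06; 0.174) passed without wild-type negative array 1 (-0.12; 0.026), p53 targets (-0.07; 0.0921) without mutant negative array 2 (-0.15; 0.0138) and sarcomere genes (-0.08; 0.21) without mutant negative array 3 (-0.14; 0.0279). Visceral endoderm genes (0.23, adjusted p = 0.326) passed without wild-type negative array 2 (0.39, adjusted p = 0.0498) and, at the same mean, without mutant positive array 1 (adjusted p = 0.00584). Trophoblast genes (0.17, adjusted p = 0.0594) passed without wild-type negative array 2, mutant negative array 3 or mutant positive array 1 or 3 (adjusted p 0.0143 to 0.0425).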

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

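The interaction was set before the data were examined, whereas the tests of explanations and of other splits given here were chosen only after the results were seen. The results below stand apart because the positive-negative difference differed between genotypes in the interaction, except for unnamed probe sets and single arrays. For 469 genes and 10 lists the difference passed limma's or camera's test. With the 6 positive-negative pairs as units there are 10 splits, too few for a share under 0.05. The real split gave 469 genes and 10 lists, and the others at most 0 genes (by limma, at an adjusted p under 0.05) and 9 lists. Among 100 splits of single arrays, which break the pairs and so do not decide about chance, 1 gave as many genes, the real one, with at most 313 elsewhere, and 29 gave as many lists, with at most 14.

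Heart and lateral plate genes were higher in mutant than in wild-type positive cells. The means were 1.15 log2 for cardiac regulators, 1.44 for sarcomere genes (camera adjusted p = 0.0736 with an estimated correlation) and 1.05 for lateral plate genes. Their interaction means were 1.38, 1.52 (camera adjusted p = 0.0617 with an estimated correlation) and 1.32. The interaction also takes in mutant minus wild-type negative cells, where the means were -0.23, -0.08 and -0.26. Loss of blood and endothelial cells that raises every other cell type alike is argued against: the mean of 37 cardiac and lateral plate genes was 1.12 log2 higher in mutant positive cells and that of 53 neural, somite and epithelial genes 0.17 higher, a difference of 0.948 (SD 0.311 between arrays). The neural, somite and epithelial lists were lower in positive than in negative cells of both genotypes (neural means -1.43 in wild types and -1.66 in mutants). They may therefore not report other cell types of the positive fraction. Loss that raises only other reporter-positive cell types stays open. Negative cells carried into the mutant positive sort are argued against by the level of these lists, 1.42 log2 higher in mutant positive than in mutant negative cells (SD 0.0741). For the cardiac regulators alone, RNA integrity as the whole cause is argued against by their mean with the actin 3′ minus 5′ signal as a covariate, 1.13 log2 (camera adjusted p = 2.85e-14) against 1.15 without it. With this covariate Isl1, Foxf1 and Hand1 did not pass between positive cells, whereas Gata4, Tbx5 and Tnnt2 did. The Foxf1 and Hand1 calls were lost under 13 and 23 of 26 alternatives, so their loss here says little about RNA integrity. In the interaction, Tnnt2, Isl1, Foxf1 and Msx2 did not pass with the covariate, whereas Gata4 and Tbx5 did. A different mix of cells in the positive fraction and a changed state of the same cells both stay open, since sorted bulk RNA cannot tell them apart.

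Mutant positive array 1 held yolk sac endoderm transcripts, with Afp at 11.98 and Ttr at 12.21, against at most 5.02 and 5.79 on the other mutant positive arrays. Carried-over negative cells like those on mutant negative array 1 are argued against as the whole source. The visceral endoderm list lay 0.759 log2 above that array (16 of 17 genes higher, SD 0.0634 between mutant negative arrays). As a whole, however, mutant positive array 1 correlated at 0.9878 with mutant negative array 1, against 0.9858 and 0.9817 with the other mutant positive arrays. Carry-over in part into mutant positive array 1 therefore stays open. Visceral endoderm cells in that sort, which a clean EYFP sort would remove unless they carried the reporter, are a possible source. Epithelial genes were 0.743 log2 higher than on the other mutant positive arrays, which differ by 0.0398, but neural genes were also 0.594 higher, where the others differ by 0.13, so this source stays open.

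Mutant negative array 2 held embryonic globins, with Hbb-y at 11.55 and Hbb-bh1 at 10.51. The array's deviations from its group mean correlated at r = 0.403 with those of mutant positive array 2, at 0.244 with wild-type negative array 1 and at most at 0.0969 with a wild-type positive array, across genes, which are not independent replicates. A wild-type embryo under a mutant label stays open, since the labels do not say whether arrays of the same number share embryos, and since its values as a whole correlated at 0.989 to 0.991 with the wild-type negative arrays and those of the other mutant negative arrays at 0.982 to 0.986, although each mutant negative array correlated more with wild-type negative arrays than with its own group. The excess of the globins over the other mutant negative arrays, relative to that on wild-type negative array 1, was 1.69 for Hbb-y, 1.40 for Hbb-bh1 and 1.81 for Hba-x. The highest of these was 1.29 times the lowest, but relative to wild-type negative array 3 the values were 0.763, 0.376 and 0.129, a 5.93-fold spread, so erythroid RNA in that sort stays open too.

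The other interaction results are given as values. Endothelial genes had a mean of -2.54 log2, with Cdh5 at -5.34, Sox7 -5.12, Mmrn2 -5.04, Cldn5 -4.87, Fli1 -4.10, Flt4 -3.69 and Tek -2.42. Haematopoietic regulators had a mean of -1.20, with Tal1 at -4.50, Hhex -3.98, Klf1 -3.60, Lyl1 -3.25, Lmo2 -2.11 and Gata1 -1.75. Erythroid genes had a mean of -2.82, with Hemgn at -5.74, Hba-x -5.25, Slc4a1 -5.11 and Ermap -2.02. Ctla2b had -6.11, Ctla2a -5.61, Klhl4 -5.36, Etv2 -3.36, Tgfbr2 -2.39 and Atf3 -2.11. Among cardiac regulators, Tbx2 had 2.91, Wnt2 2.17, Hand2 1.85, Gata6 1.72, Gata4 1.70, Tbx5 1.52 and Isl1 1.16. Among sarcomere genes, Myl7 had 2.69, Tnni1 2.59, Ryr2 2.45, Tnnt2 2.38 and Mybpc3 1.23. Among lateral plate genes, Vcam1 had 2.79, Prrx1 2.23, Pdgfra 1.93, Msx2 1.49, Bmp4 1.41 and Foxf1 1.26. Outside these lists, Lpar3 had 2.99, Zic1 2.82, Tcf21 2.71 and Sh3bgr 2.60.

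Wnt genes had a mean of 0.52 (adjusted p = 0.0825 with an estimated correlation), with Sfrp1 at 2.38 and Axin2 at 1.03. Epithelial genes had a mean of 0.44, with Krt8 at 1.06, and the neural gene Irx3 had 0.76. The epithelial call was lost with an estimated correlation (adjusted p = 0.595), with fry (0.397), and without wild-type positive array 1 (adjusted p = 0.148), mutant positive array 1 (0.198) or mutant negative array 3 (0.0921). Notch genes had a mean of -0.28, with Notch1 at -1.63, Nrarp -1.52 and Hey1 -0.85, and this call was lost with an estimated correlation (adjusted p = 0.0886) and without wild-type positive array 1 or 2, mutant positive array 1 or mutant negative array 1 (adjusted p 0.0552 to 0.0793). BMP genes had a mean of 0.27, and that call was lost with an estimated correlation (adjusted p = 0.135), with fry (0.074), and without wild-type positive array 1 or 3, wild-type negative array 2, mutant positive array 2 or mutant negative array 1 (0.0554 to 0.0847). Of the genes named here, Isl1, Krt8, Msx2 and Hey1 did not pass under 14, 15, 15 and 14 of 26 alternatives (adjusted p up to 0.124, 0.146, 0.132 and 0.146). Tnnt2 did not pass under 10, Zic1 9, Bmp4 8, Ryr2, Irx3 and Notch1 6 each, Axin2 5, Gata4, Foxf1 and Sh3bgr 2 each, and Lmo2, Myl7, Lpar3 and Tcf21 1 each (adjusted p up to 0.154).

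Of the 9160 probe sets without a name in the platform table, 96 passed for wild-type positive against negative cells (63 higher, 33 lower), 66 for mutant against wild-type positive cells (22 and 44), 18 for mutant positive against negative cells (10 and 8), 22 in the interaction (2 and 20), and 0 between the negative cells.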

How the results depend on the processing

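The settings compared here were chosen before the data were examined, except the blocks within a genotype, the actin covariate and the omission of 2 arrays at once, which were chosen only after the results were seen. Excluding single arrays left out, named genes kept their direction and their side of the threshold in 7271 comparisons with an alternative, crossed to passing in 95 and to not passing in 237; lists did so in 1038, 12 and 63. With single arrays left out, the counts were 6028, 43 and 301 for genes and 1193, 25 and 42 for lists. No gene or list reversed among calls. Of 288 named gene calls, 209 held under every alternative run and 234 under those leaving out no array. Signal over background was not given for these arrays, and 3 arrays per group limit small changes.

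Requiring at least 2-fold left 749 genes in wild types, 647 between positive cells and 543 in mutants, and an adjusted p under 0.01 left 796, 657, 463 and, in the interaction, 214, both by construction. With only the arrays compared, 844 genes passed between positive cells, with fewer arrays to estimate the spread. With an estimated correlation, 5 lists passed between positive cells, 7 in mutants, 1 between negative cells and 5 in the interaction, and fry passed 0 between negative cells, where limma passed 0 genes (949 at an unadjusted p under 0.05). The cause was not tested.

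The replicate block over all groups gave 1511 genes in wild types, 1641 between positive cells, 1042 in mutants, 0 between negative cells and 501 in the interaction. The replicate block within a genotype gave 2160 genes in wild types (1119 higher, 1041 lower, against 843 and 656 without it), 1486 in mutants and 797 in the interaction as a fixed block, and 2220, 1514 and 842 as a random block (consensus correlation 0.272). As a fixed block it added the calls of Plac1 (adjusted p = 0.0337) and removed that of Pcna (0.0548) in wild types. In mutants it added Tal1, Lmo2, Apoe, Ccne1, Birc5, Cdkn1a, Adm and Ndrg1 (0.00376 to 0.0441) and removed Cbfa2t3, Pmaip1 and Zmat3 (0.0588 to 0.0638). In the interaction it added Hbb-bh1, Nkx2-5, Lhx1, Dll1, Krt18, Krt19, Slc39a8, Nes, Sox9, Peg10, Phlda2, Bambi and Dkk1 (0.0128 to 0.0475). This fixed block changed no other call of a named gene or list.

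With the actin covariate 908 genes passed between positive cells, 693 in mutants, 1508 in wild types and 342 in the interaction (102 higher, 240 lower). Without the covariate the counts were 1450, 975, 1499 and 469 (177 higher, 292 lower). Without both wild-type arrays numbered 1, 760 passed in wild types. The causes were not tested. Without mutant positive array 1 and mutant negative array 2, 4 genes passed between negative cells, chosen after their values were seen except Ripply2: Asl (0.98 log2, adjusted p = 0.0375), Far1 (-1.20, 0.0375), H2-Bl (1.46, 0.0353) and Ripply2 (1.96, 0.037), against adjusted p 0.884 to 0.929 on all arrays. Leaving out 1 array at a time gave 1026 to 1484 genes in wild types, 1032 to 1589 between positive cells, 677 to 1000 in mutants, 0 to 2 between negative cells (H2-Bl and Ripply2, without mutant negative array 2) and 299 to 486 in the interaction, lowest without wild-type negative array 2. The lists numbered 10 to 13, 7 to 13, 13 to 14, 4 to 9 and 7 to 11, and the correlation of the wild-type and mutant differences 0.384 to 0.436.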

Other observations

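The tests in this part were chosen only after the results were seen. Hox genes, which pattern the body axis, were chosen after their values were seen, and a difference between the paralog groups below was not tested. The values compare mutant positive with mutant negative cells. Of 23 genes of paralog groups 1 to 9, 7 were lower and 0 higher (median -0.44 log2), among them Hoxd3 (-1.20 ± 0.16, limma adjusted p = 0.00135) and Hoxc4 (-1.56 ± 0.22, 0.00185). Of 10 genes of groups 10 to 13, 3 were higher and 0 lower (median 0.56): Hoxc10 (2.90 ± 0.50, adjusted p = 0.00571), Hoxd10 (1.12 ± 0.26, 0.0267) and Hoxa10 (1.56 ± 0.41, 0.0493), all of paralog group 10. Members of both ranges went the other way without passing, such as Hoxb5 (0.61), Hoxb6 (0.79), Hoxd8 (0.41) and Hoxd9 (0.50) in the first and Hoxd12 (-0.16) and Hoxc13 (-0.09) in the second. In wild types, 8 of the first group were lower and 2 higher (median -0.53), and 0 of the second group passed (median 0.21). Hoxa10, Hoxc10 and Hoxd10 did not pass in the interaction (0.98, 1.99 and 0.53 log2, adjusted p = 0.565, 0.239 and 0.652), so a difference between genotypes was not shown.

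A hypothesis was tested that mesodermal cells move from the negative to the positive sort in mutants, which would lower in mutant negative cells the genes raised in mutant positive cells. The 769 genes higher in mutant than in wild-type positive cells had a median difference of 0.0216 log2 between mutant and wild-type negative cells, against 0.0291 for 10000 random lists matched on expression, at percentile 15.8, which decides nothing. The mean of the lateral plate list, relative to the mean over arrays, was -0.421, -0.294 and -0.226 on wild-type negative arrays and -0.493, -0.498 and -0.744 on mutant negative arrays.

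With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Wild-type positive against negative cells gave 1499 genes, with at most 1 in another split, and 11 lists, with at most 12 (2 splits gave as many). Mutant against wild-type positive cells gave 1450 genes against at most 4, and 10 lists against at most 13 (2 splits). Mutant positive against negative cells gave 975 genes against at most 0, and 14 lists against at most 9 (1 split). Mutant against wild-type negative cells gave 0 genes by limma, with 949 at an unadjusted p under 0.05 and at most 2 in another split, and 6 lists against at most 7 (3 splits). The other splits that part all 3 positive-negative pairs gave at most 0 genes and 9 lists in each genotype.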
